A study of Arabidopsis thaliana with 9 samples.

How the data were processed

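Gene expression was measured in whole rosettes of 4-week-old Arabidopsis thaliana plants grown with 16 h of light and 8 h of darkness. Per the labels, 3 genotypes were sampled with 3 replicates each: wild type (WT), a line named for overexpression of the AP2/ERF transcription factor TINY (TINYOE), and a mutant line named for lesions in tiny1, tiny2 and tiny4 (tiny124). Libraries were made from about 500 ng of total RNA with the QuantSeq kit, which sequences 1 fragment near the 3' end of each polyadenylated transcript, and were read as single 50 nt reads. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be technical.

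The deposited counts are whole numbers of reads per gene, not normalized. Per the labels, reads were trimmed and mapped to the TAIR10 genome with the BlueBee Lexogen QuantSeq FWD pipeline, version 2.2.2, and the aligner and annotation inside it are not given in the sources used here. The authors also deposited DESeq2 tables for TINYOE against WT and tiny124 against WT, a tool that the submitters' processing notes name without a version. Per the file headers, these tables hold the counts again, normalized counts, a fold change, its log2 value, a p-value and an adjusted p-value. The normalized counts of the deposited tables were rounded to whole numbers and were treated as a score with no fixed range, as were the dispersion values. The ratio columns of the deposited tables hold the fold change of the mutant or overexpression line over WT. The deposited log2 fold changes and the deposited p-values were used only to set the authors' calls beside the present ones. The 2 tables together hold 8 libraries, and WT replicate 2 is the library they do not hold. Their 4 dispersion columns are identical in both tables.

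The count table held 32833 genes, of which 32548 were found by locus ID in the reference annotation. That annotation belongs to TAIR10.1, a different release from the one the labels name, and was used only for gene symbols and for the order of genes along chromosomes. No coordinates are given for that reason, and the digit after AT in a locus ID is its chromosome. Genes were kept with edgeR's filterByExpr, which left 16434 genes. The genes dropped held 0.296% of all counts. Library totals ranged from 4917868 to 6070778 counts. With depth of this order, genes at or under 1 CPM (counts scaled by the effective library size) were represented by few reads, and small differences in them were not detectable.

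The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM normalization. All 9 libraries entered 1 fit with genotype as the only term and 6 residual degrees of freedom, so the genotypes shared an estimate of the spread. The common biological coefficient of variation was 0.18. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Unless another test is named, an adjusted p of a gene is from this test. CPM values are given as mean ± SD of 3 libraries, with TMM-scaled library sizes, and ± after a log2 fold change is its standard error. A fold against a genotype with 0 counts was computed against 3 counts over that genotype's libraries and is a lower bound that covers counting error only.

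Before the data were examined, 20 gene lists with 430 loci were fixed, 372 of which were tested. They covered the TINY family, brassinosteroid biosynthesis and signalling, cell wall loosening, auxin, gibberellin, jasmonate, salicylate and defence, ethylene, dehydration and ABA, cold, touch and wound response, photosynthesis, the circadian clock, senescence, glucosinolates, flavonoids, the cell cycle, inflorescence and flower markers, and root markers. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists in each comparison. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule also fixed then. It took the tested TINY family members, the 8 higher and 8 lower genes with a symbol and the largest change among those with a mean of at least 5 CPM and no overlap between genotypes, and up to 3 called members of each list, or 1 member where none was called. For TINYOE against tiny124 it took 5 genes in each direction and up to 10 genes called in opposite directions against WT. Genes outside the rule are named as list members or as chosen after their values were seen.

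The alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, fits of the 6 libraries compared only, the replicate number as a block, and leaving out each library in turn. Fits without the genes of a segment of chromosome 1 were added after the data were seen. Because both comparisons against WT used the same WT libraries, 30 data sets with unchanged genotypes were simulated to give the overlap that arises when no gene changes. A scan for runs of neighbouring genes that were higher or lower together was also added after the data were seen, with 1000 shuffles of gene order.

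The steps were tested on simulated data drawn from the real means, depths and dispersions. For TINYOE against WT, with 16155 genes run, 93.9% of genes changed 4-fold, 53.7% of genes changed 2-fold and 4.48% of genes changed 1.5-fold were recovered. For tiny124 against WT, with 16165 genes run, the shares were 93.9%, 28.4% and 2.99%. For TINYOE against tiny124, with 16136 genes run, they were 90.9%, 44.8% and 8.96%. Of the simulated calls, 3.81%, 7.78% and 3.03% were false in the 3 comparisons, in that order. In each set 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. The real TINYOE against WT comparison had 2561 calls. With fewer changed genes the adjusted threshold is stricter, so the recovered shares need not carry over to the real data.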

Results

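The series measured 3' mRNA tags in whole rosettes of WT, TINYOE and tiny124 plants, with 3 libraries per genotype. Its title names brassinosteroid-regulated growth and the drought response as its subject. Total counts were 5557064, 4917868 and 5548380 in WT replicates 1, 2 and 3, 5742611, 5500292 and 5794432 in TINYOE, and 5217176, 6070778 and 5686041 in tiny124. On the first principal component, which held 43.0% of the variance, WT replicates 1 and 3 lay at -53.91 and -31.48, WT replicate 2 at 0.53, the tiny124 libraries between -31.96 and -6.82, and the TINYOE libraries between 39.17 and 53.16.

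The targeted genes were examined first. TINY (AT5G25810) had 20, 18 and 25 counts in WT, 33, 35 and 27 in TINYOE, and 3, 5 and 4 in tiny124. In tiny124 it stood at 0.706 ± 0.132 CPM (SD, n = 3) against 4.06 ± 0.45 in WT, a log2 fold change of -2.48 ± 0.37 (adjusted p = 0.00168). In TINYOE it stood at 5.39 ± 0.762 CPM, and the log2 fold change of 0.40 ± 0.27 did not pass the test (adjusted p = 0.343). TINY2 (AT5G11590) was removed by the filter on low counts, with 5, 7 and 11 counts in WT, 2, 1 and 0 in TINYOE, and 1, 0 and 0 in tiny124. The ratio of its depth-scaled counts to WT was 0.114 in TINYOE (95% exact interval 0.022 to 0.378) and 0.0398 in tiny124 (0.000967 to 0.245), intervals that cover counting error only. In the fit without a filter its adjusted p was 0.0156 in TINYOE and 0.00862 in tiny124. In that fit each gene took the spread of the trend in place of its own, which can make p too small. There TINY had an adjusted p of 1.14e-05 in tiny124, against 0.00168 in the main fit. The labels do not tie the third mutated gene to a locus. Among the other family members, AT4G32800 fell in tiny124 (log2 fold change -2.86, adjusted p = 0.00017) and in TINYOE (-1.48, adjusted p = 0.00201). AT2G44940 also fell in tiny124 (-1.55, adjusted p = 0.00672) and in TINYOE (-2.52, adjusted p = 6.21e-05). AT4G16750 fell in TINYOE (-1.44, adjusted p = 0.00761), was at -0.05 in tiny124 (adjusted p = 0.976), and differed between the lines (-1.39). A 3' tag outside a deleted part, or a transgene with another 3' end, would leave these counts uninformative about the lesion or the transgene. The TINYOE label was therefore not checked by TINY's own tags.

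**Figure D1:**
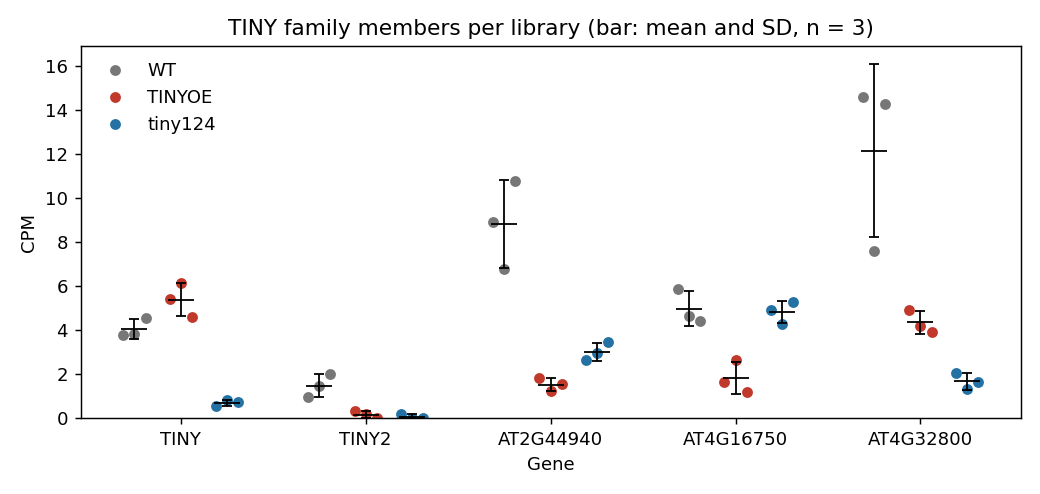
Expression in CPM (vertical axis) of 5 TINY family genes (horizontal axis) in the 9 libraries; points are libraries, and bars give the mean and SD of 3 libraries per genotype. TINY lay at 0.706 CPM on average in tiny124 against 4.06 in WT and 5.39 in TINYOE.

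TINYOE against WT addressed what accompanies the overexpression that the line is named for. The jasmonate (13 of 25 genes lower), glucosinolate (16 of 23) and flavonoid lists (8 of 13) were called lower in TINYOE rosettes by camera, and the salicylate (11 of 23 genes higher), touch and wound (9 of 18) and senescence lists (6 of 15) higher. These list calls were lost with an estimated correlation, with adjusted p from 0.114 to 0.25. XTH20 (AT5G48070), a xyloglucan-modifying cell wall enzyme, had 0 counts in all WT and tiny124 libraries and 25.5 ± 4.02 CPM in TINYOE, at least 131-fold higher than in WT. BT2, a nitrate- and sugar-responsive scaffold protein, rose from 24.6 ± 14.1 to 420 ± 17.7 CPM, and SEN1, a gene induced by darkness, rose from 24.4 ± 6.87 to 210 ± 28.2 CPM. DFR and LDOX, enzymes of anthocyanin synthesis, fell 14.6-fold and 8.53-fold. WT replicate 2 was the lowest WT library in both, at 7.2 CPM for DFR against 45 and 33 in WT replicates 1 and 3, and at 1.91 CPM for LDOX against 14.4 and 12.8. In all, 1339 genes were higher and 1222 lower, of which 807 and 540 differed at least 2-fold.

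The other genes of largest increase were GRXS13, a glutaredoxin (log2 fold change 3.52 ± 0.27), SIS (3.04 ± 0.28), the glycine-rich protein gene GRP9 (2.99 ± 0.31), the ubiquitin ligase gene RMA2 (2.85 ± 0.44) and NIMIN1, an interactor of the salicylate co-activator NPR1 (2.72 ± 0.26). The largest decreases were in the jacalin-related lectin genes JAL23 (-4.79 ± 0.58) and JR1 (-2.97 ± 0.30), ICME-LIKE2 (-3.84 ± 0.42), the beta-amylase gene BAM5 (-3.69 ± 0.43), the myrosinase-binding protein gene MBP1 (-3.24 ± 0.41) and the defensin gene PDF1.2 (-2.81 ± 0.40). The adjusted p of the genes of largest change, XTH20, BT2, SEN1, DFR and LDOX included, lay between 1.12e-06 and 0.00182. PDF1.2 has near-identical copies, so its counts are uncertain. Among the WT libraries, replicate 2 was lowest in JAL23 (6.14 CPM against 30.6 and 21.3), JR1 (91.3 against 263 and 184), BAM5 (7.62 against 23.4 and 15.6) and MBP1 (28 against 117 and 61.8). It lay between the others in ICME-LIKE2 (9.53 against 18 and 7.33) and was highest in PDF1.2 (31.3 against 10.6 and 15.9). Of the genes of largest increase it was highest in BT2, SEN1, GRXS13, SIS and RMA2 and lay between the others in GRP9 and NIMIN1. Without WT replicate 1 the log2 fold change of MBP1 was -2.62, and without TINYOE replicate 2 that of DFR was -4.58 in place of -3.87.

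Of 25 tested jasmonate genes 13 fell and 1 rose (16 and 1 adjusted over the list alone), with a median log2 fold change of -0.85 (camera adjusted p = 3.38e-08, adjusted p = 0.114 with an estimated correlation). VSP1, a storage protein gene induced by jasmonate and a close copy of VSP2, fell 6.13-fold, and AOS, an enzyme of jasmonate synthesis, fell 2.85-fold, while the lipoxygenase gene LOX4 rose (1.58). In the salicylate list 11 of 23 genes rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 1.09e-10, adjusted p = 0.166 with an estimated correlation). NIMIN1 rose 6.58-fold, SARD1, a regulator of salicylate synthesis, 3.47-fold, and LURP1 3.14-fold. Other list members, PR2, PR5 and DMR6, overlapped between TINYOE and WT libraries. They stood at 97.3 to 200, 52.1 to 150 and 83.6 to 94.3 CPM in TINYOE. In WT they stood at 105 to 272, 48.8 to 169 and 63.6 to 94 CPM. Of 16 ethylene genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.117) but was by fry (adjusted p = 0.00941), which does not compare a list with other genes. ORA59, a factor that joins ethylene and jasmonate signals, fell 3.68-fold and the ethylene-forming enzyme gene EFE 2.11-fold. RTE1 rose 1.85-fold, and its adjusted p ranged from 0.00111 to 0.13 with single libraries left out, above the threshold without WT replicates 1 and 3 or TINYOE replicates 2 and 3.

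Of 23 glucosinolate genes 16 fell and 1 rose (16 and 2 adjusted over the list alone, median -1.11, camera adjusted p = 1.14e-14, adjusted p = 0.114 with an estimated correlation). MYB29, a regulator of aliphatic glucosinolates, fell from 21.3 ± 2.01 to 3.07 ± 0.647 CPM, and the biosynthetic genes CYP79F1 and FMOGS-OX1 fell 5.32-fold and 6.15-fold. The exception was MYB51, a regulator of indolic glucosinolates, which rose (1.495). Among 13 flavonoid genes 8 fell and 0 rose (11 and 0 adjusted over the list alone, median -1.48, camera adjusted p = 6.65e-09, adjusted p = 0.114 with an estimated correlation). They included CHS, which opens the pathway (2.94-fold), and the anthocyanin transport gene GSTF12 (7.47-fold).

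In the touch and wound list 9 of 18 genes rose and 0 fell (10 and 0 adjusted over the list alone, median 0.85, camera adjusted p = 2.13e-05, adjusted p = 0.25 with an estimated correlation). The calmodulin-like genes TCH3 and CML37 rose 1.93-fold and 5.88-fold and BAP1 3.2-fold. The log2 fold change of CML37 was 2.56, and 3.21 without WT replicate 2. Of 15 senescence genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 5.27e-05, adjusted p = 0.114 with an estimated correlation), with ASN1 at 3.96-fold and SAG21 at 2.99-fold. Of 25 auxin genes 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.00147, adjusted p = 0.134 with an estimated correlation). GH3.5, which conjugates auxin, rose 4.52-fold, SAUR21 rose 2.56-fold, and the repressor gene IAA17 fell 3.13-fold. SAUR genes are close copies of each other, so their single counts are uncertain.

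The cell wall list held 9 higher and 6 lower genes of 31 (12 and 7 adjusted over the list alone, median 0.27, also with XTH20 at its bound, camera adjusted p = 0.0309). Its adjusted p was 0.277 with an estimated correlation and ranged from 0.00263 to 0.277 over the alternatives. The call was also lost with DESeq2 (0.0915) and without WT replicate 1 (0.0565), WT replicate 2 (0.123) or TINYOE replicate 2 (0.0836). EXPB3, an expansin, rose 6.28-fold and XTH22 4.16-fold. Of 41 photosynthesis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 0.00148, adjusted p = 0.222 with an estimated correlation). The list was not called without WT replicate 2 (adjusted p = 0.0724, range 3.7e-06 to 0.222 over the alternatives). RBCS2B, uncertain because of its near-identical copies, fell 1.86-fold and PSAG 1.64-fold. Plastid-encoded genes took between 3.674% and 3.991% of counts in TINYOE against 5.344% to 5.669% in WT and 5.085% to 5.501% in tiny124. These shares were not tested. The kit reads polyadenylated transcripts, so they do not measure plastid gene expression as a whole. The TINY family list fell, with 3 of 4 tested genes lower (3 adjusted over the list alone, median -1.46, camera adjusted p = 0.00147, adjusted p = 0.139 with an estimated correlation).

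WT replicate 2 differed from the mean of the other WT libraries in the direction of TINYOE in several of these lists. The median log2 difference was -0.205 for jasmonate, -0.188 for glucosinolate, -0.525 for flavonoid, 0.430 for salicylate, 0.241 for touch and wound, 0.299 for senescence, 0.241 for auxin and -0.317 for TINY family genes. It ran in the other direction for photosynthesis genes, at 0.207, and for cell wall genes, at -0.060. In the jasmonate list WT replicate 1 was lower still, at -0.298. Among lists not called in TINYOE, WT replicate 2 was at -0.514 for inflorescence, -0.429 for root and -0.383 for cell cycle genes.

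Neither brassinosteroid list, the subject of the series, was called by camera, and fry called the signalling list higher (adjusted p = 0.0122, with 16 of 17 genes above 0). Of 12 biosynthesis genes DWF1 fell 1.66-fold (adjusted p = 0.0213) and ROT3 rose 2.38-fold (adjusted p = 0.0458), 1 each adjusted over the list alone, with a median of -0.11 and a mean of 0.02 (list adjusted p = 0.822, direction down). Of 17 signalling genes BEH4 rose 2.23-fold and BKI1 1.59-fold (adjusted p = 0.0462), 1 of them adjusted over the list alone, with a median of 0.24 (list adjusted p = 0.0863). That list was called without WT replicate 1 (0.0378) and without a filter (0.0446), within a range of 0.0378 to 0.321. BEH4 lies in the segment of chromosome 1, described below, that was higher as a block. Without that segment, a fit chosen after the data were seen, the camera adjusted p of the list was 0.166. The list holds receptor, transcription factor and inactivation genes together, so its direction does not measure the activity of the pathway. With single libraries left out, DWF1 (adjusted p 0.000803 to 0.0864) lost its call without WT replicates 1 and 3 or any TINYOE library. ROT3 (0.0211 to 0.197) and BKI1 (0.0425 to 0.126) each lost theirs without 7 of the 9 libraries, with DESeq2 (0.103 and 0.11) and with the 6 libraries compared only (0.0712 and 0.0728), and BKI1 also without a filter (0.0775).

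In the dehydration and ABA list 4 genes rose and 4 fell of 28 (7 and 5 adjusted over the list alone, median -0.01, adjusted p = 0.435), and RD20, GOLS1 and RD22 fell 4.18-fold, 2.82-fold and 1.99-fold. Of 10 cold regulon genes edgeR called 0, DESeq2 called 1, and 2 had an unadjusted p under 0.05 (list adjusted p = 0.53). KIN2 stood at -0.48 (adjusted p = 0.0507) and was called without WT replicate 1 or 2, within a range of 0.0168 to 0.242, and also with DESeq2 (0.0208), DESeq2 size factors (0.049), no filter (0.0495) and the filter of at least 5 CPM (0.0498). The gibberellin list (adjusted p = 0.66, direction down) had a median of 0.20 and a mean of -0.07, with 1 higher and 2 lower genes of 12 (1 and 2 adjusted over the list alone). RGL1 fell 4.15-fold and GASA1 2.4-fold, and GASA6 rose 1.92-fold. In the clock list (adjusted p = 0.145) 6 genes fell and 1 rose of 23 (6 and 1 adjusted over the list alone), with LHY 3.55-fold, LNK1 2.32-fold and PRR9 4.54-fold lower, and the list was called by fry (0.0298) and without WT replicate 1 (0.0351, range 0.0351 to 0.378). Of 15 cell cycle genes edgeR and DESeq2 called 0, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.599). CYCD3;3 stood at -0.62 (adjusted p = 0.0783) and was called without a filter (0.0457) and without WT replicate 2, within a range of 0.00684 to 0.315. Markers of other organs were not called as lists. Of 15 inflorescence and flower markers 2 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.341), and the list was called without TINYOE replicate 1 (0.0281, range 0.0281 to 0.75). SEP2 rose 3.12-fold, and SPL3 and SPL5 fell 2.13-fold and 2.94-fold, SPL5 not without WT replicate 3 or TINYOE replicate 1 (0.0112 to 0.0692). Of 6 root markers edgeR and DESeq2 called 0, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.545, SCR at 0.57).

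**Figure D2:**
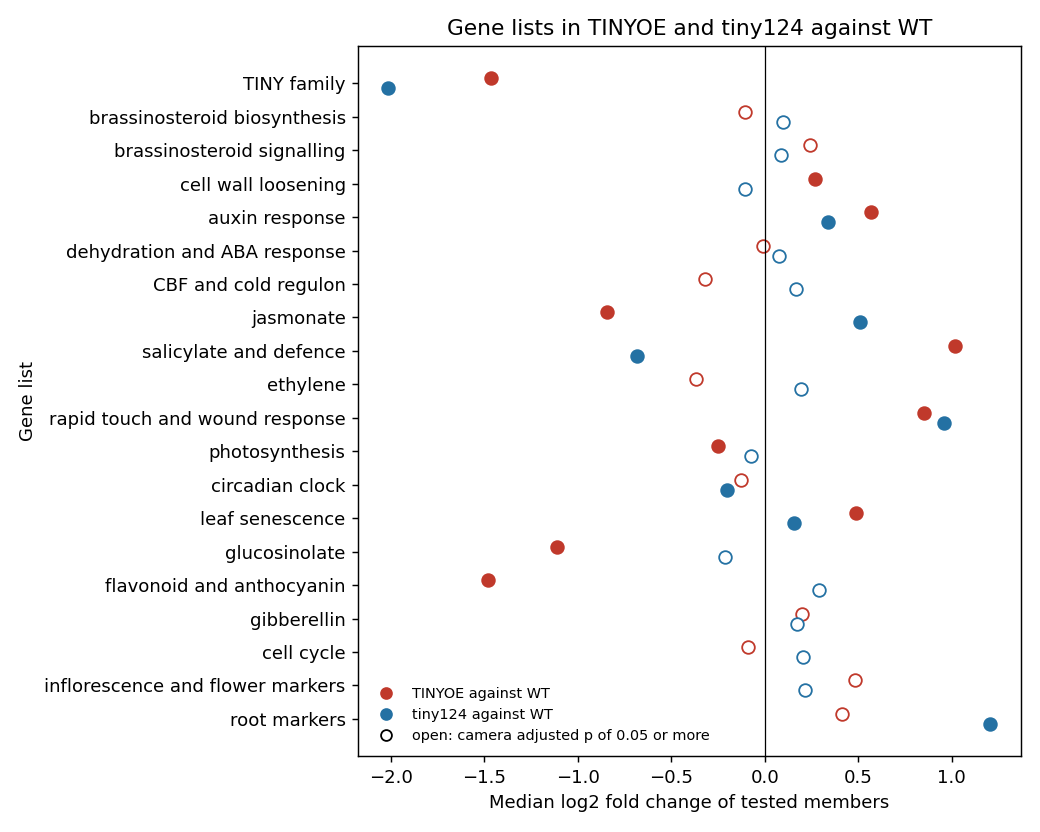
Median log2 fold change (horizontal axis) of the tested members of 20 gene lists (vertical axis) in TINYOE (red) and tiny124 (blue) against WT; filled points have a camera adjusted p under 0.05. The jasmonate list lay at -0.85 in TINYOE and 0.51 in tiny124, and the salicylate list at 1.02 and -0.69.

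A run of 194 tested genes at the end of chromosome 1, from AT1G78410 to AT1G80970, was higher in TINYOE as a block. Its median log2 fold change was 0.92 (quartiles 0.594 and 1.296), 187 genes were above 0, and 129 were called higher and 0 lower, 9.63% of all genes called higher. The 100 tested genes before it had a median of 0.01. The run holds 3 list genes, BEH4, WRKY40 and PSBR, and PSBR was the 1 photosynthesis gene that rose. Without the run, 1207 genes were higher and 1170 lower. These fits were chosen after the data were seen. They leave out the run's own genes only, so effects of the run on genes elsewhere were not tested. The other differences of TINYOE cannot be told apart from such effects here.

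**Figure D3:**
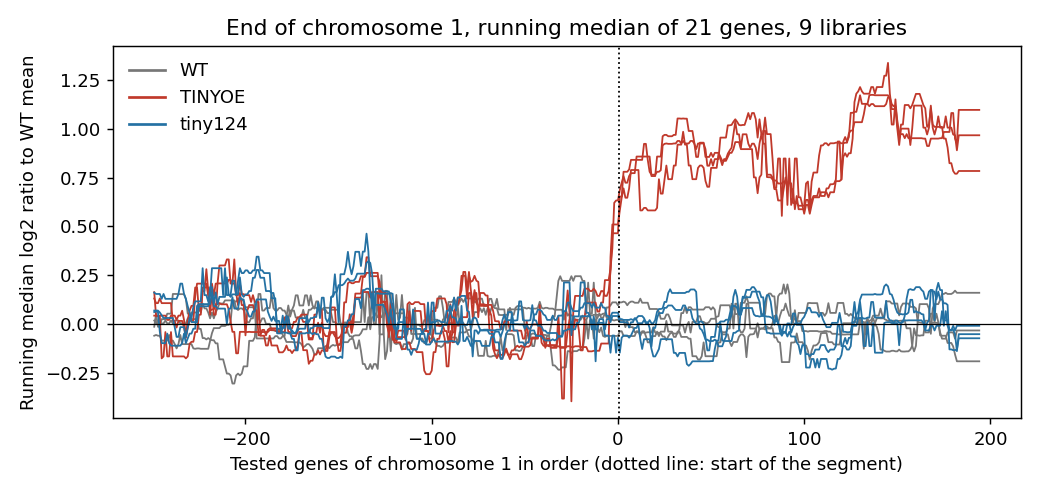
Running median over 21 tested genes of the log2 ratio of each library to the WT mean (vertical axis) along the end of chromosome 1 in gene order (horizontal axis, 0 near the start of the segment). The TINYOE libraries had segment medians of 0.933, 0.931 and 0.918, and the other 6 libraries lay between -0.040 and 0.043.

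The counts of calls depended on single libraries. Without WT replicate 2, 2141 genes were higher and 1891 lower, and without WT replicate 3, 868 and 736. The lower calls were 788 without WT replicate 1 and 746, 712 and 808 without TINYOE replicates 1, 2 and 3. In the authors' deposited table, which lacks WT replicate 2, 1742 genes were higher and 1604 lower, and 2140 of the 2561 genes called here (83.6%) were called there in the same direction, with 0 in the opposite direction.

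tiny124 against WT addressed what accompanies the lesions that the line is named for. The touch and wound (7 of 18 genes higher) and jasmonate lists (5 of 25) were called higher than in WT by camera, and the salicylate list (6 of 23 genes lower) lower. These list calls were lost with an estimated correlation (adjusted p = 0.0989, 0.0989 and 0.197). BT2 rose from 24.6 ± 14.1 to 214 ± 33.1 CPM, and CML38, a calmodulin-like gene, from 29.8 ± 5.57 to 143 ± 23.8 CPM. QQS, an Arabidopsis-specific gene linked to starch content, fell from 119 ± 10 to 9.70 ± 3.38 CPM, and DMR6, which degrades salicylate, fell from 81.9 ± 16.1 to 26.7 ± 3.31 CPM. In all, 287 genes were higher and 124 lower, of which 205 and 65 differed at least 2-fold.

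The other large increases were in CYP706A2 (log2 fold change 2.80 ± 0.33), PHI-1 (2.59 ± 0.38), the thionin gene THI2.1 (2.58 ± 0.65), MRD1 (2.57 ± 0.48), XTH22 (2.31 ± 0.27) and AIR1 (2.07 ± 0.46). The other large decreases were in the pathogenesis-related genes PR5 (-1.79 ± 0.38) and PR2 (-1.67 ± 0.32), PNP-A (-1.71 ± 0.42), WRKY54 (-1.69 ± 0.27), RLP41 (-1.63 ± 0.31) and HYH (-1.51 ± 0.27). Among the WT libraries, replicate 2 was highest in PR5 (169 CPM against 89.6 and 48.8) and PR2 (272 against 204 and 105). It was also highest in PNP-A (18.2 against 9.3 and 6.6), RLP41 (51.9 against 23.7 and 24.4) and HYH (10.4 against 8.16 and 9.72). In WRKY54 it lay between the others. Without WT replicate 2 the log2 fold change of PHI-1 was 3.29, without WT replicate 1 that of THI2.1 was 3.53, and without tiny124 replicate 3 that of AIR1 was 1.22. Several of these calls were lost with a single library left out. THI2.1 (adjusted p = 0.0459, range 0.0119 to 0.209) lost its call without WT replicates 2 and 3, TINYOE replicate 3 or tiny124 replicates 1 and 3, with DESeq2 (0.555) and with the filter of at least 5 CPM (0.0541). PNP-A (0.0396, range 0.0305 to 0.138) lost it without WT replicate 2, TINYOE replicates 1 and 3 or any tiny124 library, and with the 6 libraries compared only (0.0763). PR5 (range 0.00753 to 0.109) lost it without any tiny124 library, PR2 (0.00426 to 0.0606) without tiny124 replicates 1 and 2, and RLP41 (0.00252 to 0.0523) without tiny124 replicate 2. Without WT replicate 3 MRD1 (0.00155 to 0.0531) and AIR1 (0.00993 to 0.125) lost it, AIR1 also without tiny124 replicate 3 and with the 6 libraries compared only (0.0533).

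Of 18 touch and wound genes 7 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.96, camera adjusted p = 3.89e-18, adjusted p = 0.0989 with an estimated correlation). TCH3 rose 1.94-fold and ERF6 3.29-fold. The list was also called higher in TINYOE (median 0.855) and was not called between the lines in the main test (camera adjusted p = 0.17). Its rise was therefore not particular to tiny124. It had been fixed as a reading of plant handling, and a difference of WT in handling was not tested apart from genotype. Of 25 jasmonate genes 5 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 7.45e-09, adjusted p = 0.0989 with an estimated correlation), including LOX4 (4.08-fold), the repressor gene JAZ9 (2-fold) and VSP2 (2.65-fold). JAZ9 was not called without tiny124 replicate 1 (adjusted p = 0.0714, range 0.0053 to 0.0714), nor VSP2 without WT replicate 3 or tiny124 replicates 1 and 3 (0.00231 to 0.0964). In the salicylate list 6 of 23 genes fell and 1 rose (10 and 2 adjusted over the list alone, median -0.69, camera adjusted p = 7.45e-09, adjusted p = 0.197 with an estimated correlation and 0.112 by fry), among them WRKY54 (3.22-fold) and LURP1 (2.34-fold), while WRKY18 rose (1.02). Of 15 senescence genes 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 4.18e-05, adjusted p = 0.0989 with an estimated correlation), with SEN1, ASN1 and SAG14 at 3.23-fold, 3.28-fold and 3.05-fold.

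Of 25 auxin genes 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.000908, adjusted p = 0.114 with an estimated correlation). These were IAA2 (1.88-fold), IAA1 (2.09-fold) and GH3.5 (2.15-fold). With single libraries left out, the adjusted p of IAA2 ranged from 0.00094 to 0.0604 (not called without WT replicate 3 or tiny124 replicate 1) and that of IAA1 from 0.0138 to 0.121 (not called without WT replicates 1 and 3 or tiny124 replicates 1 and 2). That of GH3.5 ranged from 0.0386 to 0.149, and it was not called without any WT or tiny124 library or without TINYOE replicate 2, with DESeq2 (0.0565) or with the 6 libraries compared only (0.0712). In the clock list 3 of 23 genes fell and 0 rose (6 and 0 adjusted over the list alone, median -0.20, camera adjusted p = 0.00594, adjusted p = 0.181 with an estimated correlation), and its call was lost without WT replicate 2 (adjusted p = 0.0664, range 0.000217 to 0.181 over the alternatives). They were the dawn-phased genes LHY (2.27-fold), LNK1 (1.76-fold) and CCA1 (1.85-fold). All 3 lost their call without WT replicate 3 or tiny124 replicates 1 and 2, LNK1 and CCA1 also without tiny124 replicate 3, and LNK1 without WT replicate 1 or TINYOE replicate 2 and with the 6 libraries compared only (0.0552). Their adjusted p with single libraries left out ranged from 0.00131 to 0.124 for LHY, 0.0108 to 0.196 for LNK1 and 0.0107 to 0.154 for CCA1. Of 6 tested root markers 1 rose, the beta-glucosidase gene PYK10 (3.12-fold), with a list median of 1.21 (4 and 0 adjusted over the list alone, camera adjusted p = 0.00234, adjusted p = 0.181 with an estimated correlation). The root list lost its call without WT replicate 2 (0.0616) and with the filter of at least 5 CPM (0.182), with a range of 0.000825 to 0.182. In the TINY family 3 of 4 tested genes fell (3 adjusted over the list alone, median -2.01, camera adjusted p = 3.21e-10, adjusted p = 0.0563 with an estimated correlation). The list holds TINY, which the mutant is named for, and may hold the third mutated gene, so part of its fall is set by the genotype and is not independent evidence.

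The other lists were not called. In brassinosteroid biosynthesis (adjusted p = 0.527, CPD at 0.29) and signalling (adjusted p = 0.718, BES1 at 0.25) edgeR and DESeq2 called 0 genes, and 0 had an unadjusted p under 0.05. In the dehydration and ABA list (adjusted p = 0.572) RD26, a NAC factor of the drought response, rose 2.53-fold as 1 of 28 genes (1 adjusted over the list alone). The cell wall list had 3 higher and 1 lower gene (5 and 1 adjusted over the list alone), with a median of -0.11 and a mean of 0.11 (adjusted p = 0.584, direction up). XTH30 and XTH27 rose 2.63-fold and 1.68-fold, XTH30 not without WT replicate 3 (0.00808 to 0.0505) and XTH27 not without WT replicate 3 or tiny124 replicate 2 (0.0228 to 0.0936). In the glucosinolate list (adjusted p = 0.15) 1 gene, MYB51, rose 1.81-fold (1 adjusted over the list alone), but not without WT replicate 3 or tiny124 replicates 1 and 3 (0.028 to 0.13). The list was called lower without WT replicate 2 (0.0102) or tiny124 replicate 1 (0.00781), within a range of 0.00781 to 0.723.

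In the following lists edgeR called 0 genes. The flavonoid list had a median of 0.29 and a mean of 0.06, while the test's direction was down (adjusted p = 0.681, TT7 at 1.38), and 5 genes had an unadjusted p under 0.05, 1 of them called adjusted over the list alone. For gibberellin (0.261, GASA6 at -0.56) 3 genes had such a p, DESeq2 called 1, GASA6 (0.0493), and 2 higher and 1 lower were called adjusted over the list alone. Ethylene (0.206, called by fry at 0.0475, ETR2 at 1.22) had 3 genes with such a p, and cold (0.343, KIN2 at 0.42), photosynthesis (0.395, RCA at -0.41) and cell cycle (0.209, AUR2 at 1.27) had 1 each. Inflorescence markers (0.315, FUL at 0.82) had 0. DESeq2 called 0 genes in these lists except gibberellin. The photosynthesis list was called lower without WT replicate 1 (0.02, range 0.02 to 0.919).

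In this comparison too the counts depended on single libraries. Higher and lower calls were 129 and 77 without WT replicate 3, 133 and 34 without tiny124 replicate 1, 178 and 39 without replicate 2, and 176 and 64 without replicate 3. By the authors' deposited table, 279 genes were higher and 138 lower, and 266 of the 411 genes called here (64.7%) were called there in the same direction. That table lacks WT replicate 2. Its DESeq2 adjusted p was 0.252 for PR5, 0.186 for PR2, 0.318 for PNP-A, 0.243 for RLP41 and 0.129 for LURP1. It was 0.528 for VSP2, 0.213 for THI2.1, 0.0624 for MRD1 and 0.124 for AIR1, so these genes were not called there. WRKY54 (0.00415), DMR6 (0.00279) and HYH (0.00519) were.

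TINYOE against tiny124 compared the lines directly and tested whether their differences from WT differed. The jasmonate list (18 of 25 genes lower) was called lower and the salicylate list (17 of 23 genes higher) higher in TINYOE by camera. With an estimated correlation the jasmonate call held (adjusted p = 0.0358) and the salicylate call was lost (adjusted p = 0.0685). XTH20 was at least 143-fold higher, and QQS stood at 260 ± 53.5 CPM in TINYOE against 9.70 ± 3.38 in tiny124. GRP9, XTH31 and NIMIN1 were 18.6-fold, 13.3-fold and 12.3-fold higher. JAL23, BAM5, PDF1.2c, MBP1 and DFR were 63.5-fold, 34-fold, 22.3-fold, 19.8-fold and 17.9-fold lower, with PDF1.2c uncertain because of its near-identical copies. Without TINYOE replicate 2 the log2 fold change of DFR was -4.87 in place of -4.16. In all, 841 genes were higher and 777 lower, of which 516 and 452 differed at least 2-fold.

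Of 25 jasmonate genes 18 were lower and 1 higher (20 and 1 adjusted over the list alone, median -1.48, camera adjusted p = 3.08e-25), and this was the 1 list still called with an estimated correlation (adjusted p = 0.0358). In the salicylate list 17 of 23 genes were higher and 0 lower (22 and 0 adjusted over the list alone, median 1.70, camera adjusted p = 4.07e-30, adjusted p = 0.0685 with an estimated correlation). The glucosinolate list was lower, with 14 lower and 2 higher genes of 23 (14 and 3 adjusted over the list alone, median -0.99, camera adjusted p = 4.36e-14). So was the flavonoid list, with 7 lower genes of 13 (7 adjusted over the list alone, median -1.07, camera adjusted p = 8.6e-10), and the ethylene list, with 4 lower genes of 16 (6 adjusted over the list alone, median -0.45, camera adjusted p = 0.00554). Each of these 3 had an adjusted p of 0.0685 with an estimated correlation. The photosynthesis list was also lower (5 lower and 1 higher of 41, 7 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.00795, adjusted p = 0.441 with an estimated correlation and 0.0506 by fry). The cell wall list, with 8 higher and 8 lower genes (11 and 10 adjusted over the list alone), had a median of -0.23 and a mean of 0.42, the test's direction being up, and was not called (adjusted p = 0.0962). With XTH20 at its bound the mean was 0.324. The list was called with the filter of at least 5 CPM (0.00841) and with the 6 libraries compared only (0.037), within a range of 0.00841 to 0.474. The remaining lists were not called, with adjusted p from 0.127 to 0.758. Of these, senescence was called under the same alternatives (0.0264 and 0.037), touch and wound without TINYOE replicate 1 (0.0303) or tiny124 replicate 3 (0.0257), the cell cycle without TINYOE replicate 2 (0.0338), and brassinosteroid signalling without tiny124 replicate 3 (0.0376) and by fry (0.0417).

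**Figure D4:**
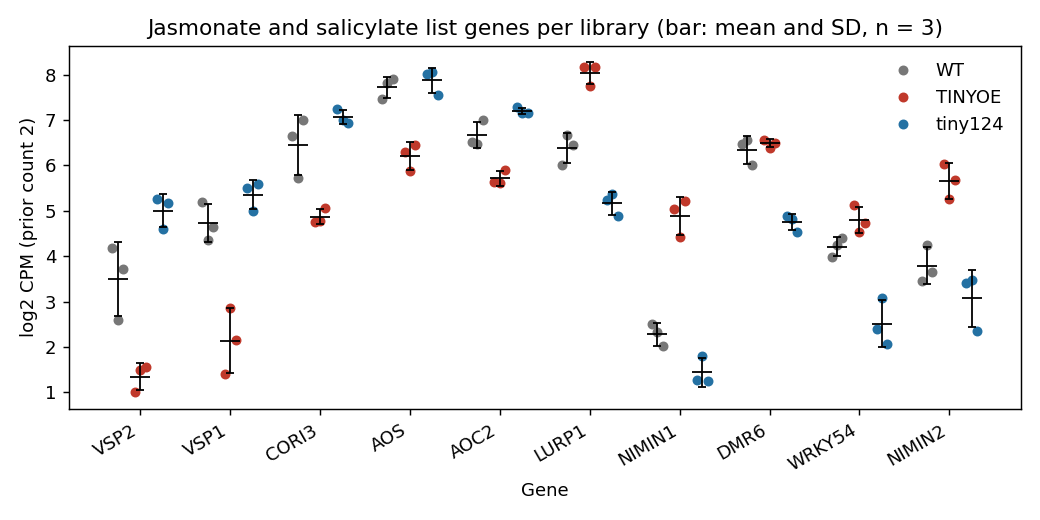
Expression in log2 CPM with a prior count of 2 (vertical axis) of the 5 jasmonate and 5 salicylate list genes with the smallest p in TINYOE against tiny124 (horizontal axis); points are libraries, and bars give the mean and SD of 3 libraries. The log2 fold change of TINYOE over tiny124 was -3.85 for VSP2 and 2.88 for LURP1.

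The calls of this comparison also moved with single libraries. Lower calls were 514, 483 and 461 without TINYOE replicates 1, 2 and 3, and higher calls 526 without TINYOE replicate 3. Without tiny124 replicates 1 and 3, higher and lower calls were 519 and 487, and 481 and 465. Without the chromosome 1 run, 701 genes were higher and 745 lower.

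Genes called in both lines against WT mostly moved the same way. Both lines shared 190 higher and 68 lower genes, 258 in all, where independent lists would share 32.6, and 20 genes were called in opposite directions, where independent lists would share 31.4. In 30 simulated sets with unchanged genotypes, edgeR gave 0 shared calls. That 0 was set in advance by the absence of changes and is no measure of the shared WT libraries. At an unadjusted p under 0.05 the simulated means were 161.1 same-direction and 0.867 opposite genes, against 1011 and 136 observed. Genes were simulated independently, with the same dispersion in all genotypes, so the simulation may understate the overlap that the shared WT libraries give. The fold changes had a correlation across genes of 0.411 (simulated 0.514) and a covariance of 0.116 (simulated 0.0455). WT could not be split into parts of at least 2 libraries, so part of the excess may come from the shared WT libraries. All 20 opposite genes were also called between the lines, which nearly follows from opposite calls against the same WT libraries and is no further support. BGLU18, TSA1 (AT1G52410), VSP2, BAM5, MSRB5 and AT1G14250 were higher in tiny124 and lower in TINYOE than in WT, and LURP1, QQS, PCR1 and AT1G13470 were lower in tiny124 and higher in TINYOE. Without WT replicate 3 the counts of shared calls were 114 in the same and 9 in opposite directions. Without WT replicate 1 there were 171 same-direction genes, and without tiny124 replicates 1, 2 and 3 there were 110, 145 and 170, with 11 opposite genes each. Opposite genes numbered 12 without TINYOE replicate 1 and 12 without TINYOE replicate 3.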

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

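The tests of the chromosome 1 segment, of WT replicate 2, and of single WT libraries and the clock behind the shared calls were chosen after the results were seen; the other splits of the libraries and the simulated shared controls were chosen before.

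Results stood out where TINYOE and tiny124 differed from WT by different amounts, as tested by the direct comparison of the lines. By list, the median log2 difference of TINYOE from tiny124 was -1.48 for jasmonate, 1.70 for salicylate and defence, -0.45 for ethylene, -0.17 for photosynthesis, -0.99 for glucosinolate and -1.07 for flavonoid and anthocyanin genes. With an estimated correlation the jasmonate list alone was still called (adjusted p = 0.0358), while the adjusted p was 0.441 for photosynthesis and 0.0685 for each of the other lists. In the TINY family it was 2.88 for TINY, 1.38 for AT4G32800 and -1.39 for AT4G16750. XTH20 was at least 143-fold higher in TINYOE. The log2 difference was 4.75 for QQS, 4.21 for GRP9, 3.74 for XTH31, 3.62 for NIMIN1, 2.88 for LURP1, 2.35 for PCR1 and 1.91 for AT1G13470. It was -5.99 for JAL23, -5.09 for BAM5, -4.48 for PDF1.2c, -4.30 for MBP1, -4.16 for DFR, -3.89 for BGLU18, -3.85 for VSP2, -3.70 for AT1G14250, -1.88 for TSA1 and -1.82 for MSRB5. Outside the TINY family these genes were picked by the size of this difference or by opposite calls against WT. Their values here are therefore no independent support.

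Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split was the 1 split with as many calls in each comparison: 2561 genes in TINYOE against WT, 411 in tiny124 against WT and 1618 in TINYOE against tiny124. The highest of the other splits gave 0 calls by edgeR in each. Those splits mix the genotypes within each group, so any difference between genotypes adds to the spread there. That 0 was therefore nearly set in advance and is no support. At an unadjusted p under 0.05 the other splits gave 189 to 1780 genes against 4990 in the first comparison, 246 to 3051 against 1904 in the second, and 205 to 682 against 3816 in the third. The split with 3051 genes set WT replicates 1 and 3 and tiny124 replicate 3 against WT replicate 2 and tiny124 replicates 1 and 2, which points to a structure of the samples besides genotype.

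The end of chromosome 1 was higher in TINYOE as a block of 194 tested genes. The scan score was 85.2 against a highest shuffled score of 8.72 (permutation p = 0.000999, the smallest that 1000 shuffles can give). Bias from expression level, length or GC content was argued against by 10000 matched sets of other genes, whose highest median was 0.149, and a single library by the lowest TINYOE median of 0.918. Extra copies of the chromosome end in this line were not tested independently: 96.4% of the genes were higher, but the bounds were picked by a scan for such runs, so this share is no support. That explanation may hold and stays open, as does any other cause that raises neighbouring genes, since no DNA was measured here.

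The 258 calls shared in the same direction by both lines were the next pattern. A single WT library as the whole cause was argued against, because the shared count stayed at least 5.94 times the number that independent lists give when any 1 WT library was left out; what the remaining WT libraries share is not covered by this test. Chance values of the shared WT libraries cannot be told apart from a shared effect for part of the overlap, as WT could not be split; the covariance exceeded the simulated one by 0.0707. WT rosettes taken at another phase of the day might also give it: dawn clock genes had medians of -0.74 in TINYOE and -0.79 in tiny124, and evening genes 0.41 and 0.403. The evening genes tested were 5, and they did not move together. TOC1, LUX and ELF4 were above 0 in both lines. GI stood at -0.431 in TINYOE and 0.002 in tiny124, and PRR5 at -0.007 and -1.035. The explanation by harvest phase stays open because the evening medians of the tiny124 libraries overlapped those of WT, a criterion added after the medians were seen, and because harvest time is not given.

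WT replicate 2 lay nearer to TINYOE than the other WT libraries on the first component, and it is the library that the authors' deposited tables lack. A mixture with TINYOE RNA was argued against by its median over the chromosome 1 segment, -0.040, and by its 0 counts of XTH20. Lower depth was argued against, since with every library thinned to 4917868 counts it stayed 31.8 units above the nearer of the other WT libraries. No biological explanation was tested.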

How the results depend on the processing

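All alternatives were planned except the fits without the chromosome 1 segment, which were chosen after the data were seen. Of 131 named gene results, 105 kept their side of the threshold under every alternative run, 26 did not, and 0 changed direction while called. DESeq2 gave no adjusted p for 4 named gene values. List calls kept their side in 954 values and changed it in 46. The cause was not tested for the changes below except where fewer libraries or genes show it. With an estimated correlation 0 lists were called in TINYOE against WT (10 in the main test), 0 in tiny124 against WT (8) and 1 in TINYOE against tiny124 (6). For the lists called in the main test the estimates ranged from 0.04 to 0.42, 0.042 to 0.41 and -0.017 to 0.45, in that order, against the preset 0.01. The highest was that of the salicylate list each time. The ethylene list in TINYOE against tiny124 lost its call at -0.017, so a higher correlation does not account for every loss. Its unadjusted camera p was 0.00139 with the preset and 0.014 with the estimated correlation. A call lost with an estimated correlation therefore does not measure the correlation between genes alone. Without a filter, tiny124 against WT had 488 higher and 218 lower genes, and shared calls were 404 in the same and 61 in opposite directions. In that fit of 25095 genes the estimated prior degrees of freedom were infinite, so each gene took the spread of the trend in place of its own. With the 6 libraries compared only, 81 genes were lower in tiny124 against WT, 1167 were lower in TINYOE against tiny124, and 170 calls were shared in the same direction. Leaving out 1 library gave 868 to 2141 higher and 712 to 1891 lower genes in TINYOE against WT, 129 to 375 and 34 to 151 in tiny124 against WT, and 481 to 1131 and 461 to 1074 in TINYOE against tiny124. Shared calls then ranged from 110 to 384 in the same and from 9 to 24 in opposite directions. The coefficient of variation fell from 0.18 to 0.161 without WT replicate 1 or without WT replicate 2, and was 0.181 to 0.191 without any other library. In the 1618 calls of TINYOE against tiny124, 1618 were kept without WT replicate 1, 1618 without WT replicate 2 and 1426 without WT replicate 3. With the replicate number as a block, 75 genes were lower in tiny124 against WT in place of 124, 217 were higher in place of 287, and no other count moved by over 1.5 times. With that block ROT3 (adjusted p = 0.0801) and BKI1 (0.0707) in TINYOE against WT, and THI2.1 (0.109), PNP-A (0.0713), IAA1 (0.0542), GH3.5 (0.0761) and CCA1 (0.0687) in tiny124 against WT, were not called. The labels do not say what libraries with the same number share. The correlations of their deviations ranged from -0.307 to 0.360, and those of libraries with different numbers from -0.415 to 0.440. These values do not show a pairing by number and cannot exclude one. In the simulated data, where few genes were changed, changes of 1.5-fold were mostly not recovered. Depth was not varied there, so a limit set by depth was not tested.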

Other observations

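Pollen coat and tapetum genes differed between libraries of one genotype. Of 10 such genes, a list chosen after the data were seen, 7 were tested, and their summed counts were 309, 62 and 298 in WT, 20, 481 and 371 in TINYOE, and 547, 516 and 573 in tiny124. By edgeR and by DESeq2 0 of the 7 were called in any of the 3 comparisons. In tiny124 against WT 4 of them had an unadjusted p under 0.05, with a median log2 fold change of 1.28, in TINYOE against tiny124 2 did, and in TINYOE against WT 0 did. In tiny124 the neighbouring genes from AT5G07510 to AT5G07560, which encode oleosin-like pollen coat proteins, gave a scan score of 5.44 over 5 genes, against a highest shuffled score of 5.24. These 5 genes are among the 7 tested members of the list, so the run and the list are not separate observations. WT replicate 2 and TINYOE replicate 1 had the lowest sums of their genotypes.

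The gene AT1G75945, outside the naming rule and chosen after its values were seen, stood at 45.5 ± 3.02 CPM (SD, n = 3) in tiny124 and 0.446 ± 0.282 in WT, a log2 fold change of 6.58 ± 0.31 (adjusted p = 4.25e-09). In TINYOE it stood at 1.303 ± 0.244 CPM. Another run of neighbours, 7 tested genes from AT3G16400 to AT3G16470, the last of which is JR1, was lower in TINYOE than in tiny124 with a median of -1.47, and its scan score of 5.995 lay below the highest shuffled score of 6.34 (permutation p = 0.004 over 1000 shuffles).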
